A study of Mus musculus with 2 samples.

How the data were processed

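Total RNA from the liver of mouse embryos at day 14.5 was sequenced in 2 biological replicates, 1 library each, in 1 group. The replicate numbers are those in the labels. Per the labels, RNA was extracted with mirVana, RNA above 200 nucleotides was used at 10 ng, a Smart-seq protocol is linked and ERCC spike-ins were added.

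The authors deposited 1 gene table and 1 transcript table per library, on mm10 with GENCODE annotation M4 per the deposited description of the files. The aligner, the counting program and their versions are not given in the sources used here. Expected counts, the estimated reads per gene, were deposited without normalization and need not be whole where a read maps to several loci. TPM, each row's length-scaled share of transcripts, was deposited over all rows, spike-ins included, and sums to the same total in each library. FPKM, fragments per kilobase scaled to the library total, was deposited beside it. The percent of each gene's TPM held by a transcript, and a posterior SD of each estimated count, in reads, were deposited too, per the file headers. The effective length used was 99 nucleotides below the length, so TPM of the shortest RNAs is inflated. Whether reads were counted by strand is not stated, so overlapping and antisense genes can share reads. Amplification can make reads non-independent, and every interval and floor covers counting error only.

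Libraries held 39998450 (replicate 1) and 28848861 (replicate 2) expected counts, of which 37059776 and 26908926 lay on 43346 mouse gene rows. The remainder lay on spike-ins, apart from 26248 rows with numeric IDs, which were left out. Symbols, biotypes and positions were taken by unversioned identifier from GENCODE M21, which uses the same build. Symbols were found for 42462 mouse rows, and the 884 rows without one held 0.114% and 0.120% of reads. Gene lists were fixed before the data were examined: 48 lists with 672 symbols, of which 662 matched directly, 4 through RefSeq synonyms and 6 not at all.

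Genes were called detected at 1 TPM. Ratios between livers were log2 of TPM plus a pseudocount of 1, replicate 2 over replicate 1, which understates differences of low genes. The count of 2-fold differences used genes with a mean of 10 TPM or more and at least 50 summed expected counts, beside 100 Poisson draws from the pooled profile. Each list's median TPM was placed among 10000 random lists of the same size drawn from genes detected in both. Each list's median ratio was placed among 10000 lists whose members were drawn from the 100 genes nearest in mean level, and a list stood apart below the 2.5th or above the 97.5th percentile; 46 lists had at least 3 measured members. With 1 group of 2 libraries no test between groups was possible and no p-value was computed. A chi-square over 16250 degrees of freedom gave 10.4 per degree between the libraries, so they are not copies of 1 library.

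Most genes named in the text were chosen by a rule fixed before the data were examined: the 20 highest, the 3 highest and the lowest of each list, the 12 largest ratios each way, every member of 6 lists (both globin lists, haem synthesis, urea cycle, oncofetal, sex-linked), and the most used transcript of fixed genes at 5 TPM or more. Not every gene of the rule is printed. Outside the rule, and named after values were seen, are Fli1, Cp, Lcn2, Lbp, Crp, Apcs, Orm1, Saa1, Saa2, Saa4, Serpina3n, Steap4 and Ddx3x. The same holds for the transcript Pklr-202 and the second transcript of Mbnl1.

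The procedures were tested on simulated libraries with the real profile, after the main analysis had first been run. With 200 of 5544 genes changed and a coefficient of variation of 10%, 100% of 4-fold and 88% of 2.5-fold changes were called at 2-fold, with 0 unchanged genes called. No reads shared between loci and no changes of effective length were simulated, so false calls from these are not covered. In 5 simulations with no change, a mean of 2.0 and at most 4 of 46 lists lay outside the central 95% of matched lists. When shifted by 0.3 (log2), 2 of 2 lists stood apart. Noise was drawn for each gene separately, so the simulations do not cover lists whose genes vary together between embryos.

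Alternatives were pseudocounts of 0.1 and 5, FPKM, CPM with TMM factors, TPM without globin genes, and TPM without mitochondrial genes and rRNA. Other filters, expected counts for shares and ratios, and each library alone were alternatives too. The CPM came from unrounded expected counts, and edgeR estimated the TMM factors from rounded ones (factors only, no test). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 were used.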

Results

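RNA of the mouse liver at embryonic day 14.5 was sequenced from 2 biological replicates of the B6NCrl strain. At this age the liver is both the developing liver and the main site of blood formation. Each library was made from 10 ng of total RNA above 200 nucleotides, with synthetic ERCC spike-in RNAs added. Per the labels, replicate 1 came from a liver collected on 17 July 2014 and replicate 2 from a liver collected on 15 July 2014. The labels describe each sample as one liver and also as pooled male and female tissue. Replicate 1 held 39998450 estimated reads and replicate 2 held 28848861, of which 37059776 and 26908926 lay on mouse genes. There was 1 group and no second group to test against, so values are given per library or as mean ± SD (n = 2), and no p-value was computed. Gene positions are on GRCm38 (mm10).

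Transcripts of red blood cells were the most abundant in both livers. The 4 adult-type globin genes, which encode the chains of adult haemoglobin, took 38.9% ± 1.3 (SD, n = 2) of mouse TPM, the length-scaled share of transcripts that each gene takes in a library. By estimated reads they took 19.6% of reads on mouse genes. Hba-a2 (ENSMUSG00000069917.7, chromosome 11, 32296489 to 32297298) stood at 139139 ± 3832 TPM and Hbb-bs (ENSMUSG00000052305.5, chromosome 7, 103826534 to 103828096) at 79324 ± 1946 TPM. Hbb-bt was at 73351 ± 2277 TPM and Hba-a1 at 58361 ± 1849 TPM. The 20 genes with the highest mean took 49.2% of mouse TPM in replicate 1 and 47.6% in replicate 2. Reads shared between copies were divided by the counting model, with a spread of at most 0.14% on the estimated counts of these 4 genes.

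Embryonic globins were expressed far below the adult type. Hbb-y was at 470 ± 69 TPM, Hbb-bh1 at 150 ± 33 TPM and Hba-x at 67.1 ± 6.2 TPM, and no read of Hbb-bh2 was counted in either library. The adult beta genes together were 285-fold above Hbb-y plus Hbb-bh1 in replicate 1 and 216-fold in replicate 2, a mean log2 ratio of 7.96 ± 0.28 (SD, n = 2). The adult alpha genes were 3211-fold and 2706-fold above Hba-x, a mean log2 ratio of 11.53 ± 0.17. From estimated reads in place of TPM the alpha log2 ratio was 11.02.

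The genes that make haem and the red cell membrane were high together. All 15 measured haem synthesis genes reached 1 TPM in both livers, with a list median of 246 TPM in replicate 1 and 285 TPM in replicate 2. Alas2, the erythroid form of the first enzyme, was at 822 ± 14 TPM, against 18.7 ± 1.7 TPM for Alas1, the form used outside red cells. The ferrochelatase gene Fech was at 506 ± 20 TPM and the mitochondrial iron importer gene Slc25a37 at 345 ± 21 TPM. All 32 measured genes of the list of erythroid membrane and regulators reached 1 TPM, with Car2 at 1998 ± 88 TPM and the band 3 gene Slc4a1 at 536 ± 56 TPM. Their list median of 117 TPM and that of haem synthesis, 266 TPM, lay at the 100th percentile of random lists of the same size drawn from detected genes, whose own median was 9.68 TPM.

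Of the red cell support lists, only that for maturation stood above the central 95% of random lists. Of the regulators of globin switching, Klf1 was at 444 ± 27 TPM and Nfe2 at 146 ± 6 TPM, while the fetal RNA-binding protein gene Igf2bp1 was at 6.03 ± 0.25 TPM. The list median of these 10 regulators was 19.5 TPM in replicate 1 and 24.4 TPM in replicate 2, at the 91.64th percentile. In the list for red cell maturation and organelle clearance, Bnip3l, a gene of mitochondrial removal, was at 372 ± 1 TPM, and the list median was 33.5 TPM, at the 98.74th percentile. The iron carrier and storage genes Trf, Ftl1 and Fth1 were at 4228 ± 30, 4090 ± 219 and 3387 ± 132 TPM, whereas Bmp6, a regulator of hepcidin, was at 0.14 ± 0.03 TPM. The iron handling list had a median of 18.1 TPM, at the 93.3th percentile.

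The liver lineage showed fetal and secreted-protein genes at high levels and the list of mature hepatocyte metabolism at a low level. Afp, the fetal counterpart of albumin (ENSMUSG00000054932.3, chromosome 5, 90490737 to 90508907), was at 6637 ± 310 TPM, and Alb (ENSMUSG00000029368.9, chromosome 5, 90460897 to 90476602) was at 2715 ± 187 TPM, so Afp was 2.48-fold above Alb in replicate 1 and 2.41-fold in replicate 2. The retinol carrier gene Rbp4 was at 1347 ± 142 TPM, and the hepatoblast and hepatocyte list took 1.80% ± 0.09 of mouse TPM. The list took 3.09% by estimated reads and 2.94% of TPM without globin genes. Genes of mature hepatocyte metabolism had a list median of 2.20 TPM in replicate 1 and 1.56 TPM in replicate 2. This was the 0th percentile of random lists of detected genes. Of its members, 14 of 26 were at 1 TPM or more in both, and the undetected members lower that rank. No read of Cyp2c29, a drug-metabolising cytochrome, was counted. The 26 members together held 427 TPM in replicate 1 and 457 TPM in replicate 2, so some lay well above the list median.

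Other liver functions varied in level. Apoa2 and Apoa1, the main proteins of high-density lipoprotein, were at 4335 ± 159 and 2726 ± 74 TPM, Apoe was at 1393 ± 124 TPM, and the apolipoprotein list median was 81.8 TPM, at the 100th percentile. In the coagulation list, with a median of 81.0 TPM at the 99.99th percentile, the kininogen gene Kng1 was at 461 ± 40 TPM and the fibrinogen gene Fga at 384 ± 39 TPM, whereas F9 was at 1.10 ± 0.16 TPM. The complement list had a median of 16.4 TPM, inside the central 95% at the 89.73th percentile, led by C3 at 170 ± 2 TPM. The urea cycle list had a median of 18.8 TPM, at the 83.16th percentile, with 7 of 7 members at 1 TPM or more in both; Ass1 was at 75.1 ± 6.4 TPM and Otc at 32.5 ± 3.8 TPM, while Cps1, the entry enzyme of the cycle, was at 2.08 ± 0.18 TPM. The bile acid list had a median of 2.95 TPM, at the 0.7th percentile, with Hsd3b7 at 37.0 ± 0.5 TPM and Cyp7b1 at 0.07 ± 0.07 TPM. Cholesterol synthesis genes had a list median of 48.2 TPM, at the 99.99th percentile, with Fdps at 195 ± 8 TPM.

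Markers of other blood cells were present at different levels. Neutrophil and granule genes had a list median of 37.0 TPM, led by S100a8 at 1093 ± 281 TPM and S100a9 at 580 ± 144 TPM. Megakaryocyte and platelet genes had a median of 16.3 TPM, led by the chemokine genes Pf4 at 378 ± 57 TPM and Ppbp at 162 ± 26 TPM. Macrophage and Kupffer cell genes had a median of 16.1 TPM, with the iron exporter gene Slc40a1 at 100.2 ± 2.1 TPM and the complement gene C1qb at 80.6 ± 1.5 TPM, whereas Cd163 was at 0.02 TPM in both. Stem and progenitor genes had a median of 3.05 TPM, with Ikzf1 at 43.7 ± 8.1 TPM and Hoxa9 at 0.29 ± 0.08 TPM. Mast cell and basophil genes had a median of 1.84 TPM, B cell genes 0.49 TPM and T and NK cell genes 0.41 TPM.

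Lists of neighbouring organs were low, and those of supporting cells varied. The endothelial list had a median of 4.57 TPM, with Egfl7 at 39.2 ± 0.3 TPM, and the stellate and mesenchymal list 6.18 TPM, with the collagen gene Col3a1 at 55.4 ± 2.3 TPM; both lay inside the central 95% of random lists, at the 4.0th and 13.9th percentiles. Mesothelial genes had a median of 2.04 TPM and bile duct genes 0.85 TPM, at the 0.18th and 0th percentiles. The 0th percentile follows from a median under 1 TPM. The growth factor gene Igf2 led the niche factors at 371 ± 48 TPM, while their list median was 2.84 TPM. List medians were 0.37 TPM for gut, 0.24 TPM for heart, 0.07 TPM for skeletal muscle, 0.06 TPM for neurons and neural crest and 0.04 TPM for pancreas, and the median of the lung list was 0 TPM.

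Proliferation genes were high in both livers. The S phase list had a median of 103 TPM in replicate 1 and 115 TPM in replicate 2, with the ribonucleotide reductase gene Rrm2 at 323 ± 9 TPM. The list of G2 and M phase had a median of 87.4 TPM, with Ube2c at 448 ± 18 TPM. The imprinted transcripts H19 and Igf2 were at 383 ± 25 and 371 ± 48 TPM, in a list with a median of 40.8 TPM. Of the oncofetal programme, Hmga1 was at 142 ± 13 TPM, Igf2bp3 at 11.3 ± 1.4 TPM, Lin28b at 6.31 ± 0.35 TPM and Lin28a at 0.28 ± 0.08 TPM, and its list median was 6.04 TPM. Medians were 12.9 TPM for the hypoxia response, 5.61 TPM for immediate early and heat shock genes and 1.24 TPM for the interferon response. Of the 48 lists, 17 had a median above and 18 a median below the central 95% of random lists. The random lists held only genes at 1 TPM or more in both livers. A list with a median under 1 TPM was therefore below them in advance, and its rank adds nothing to its median.

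**Figure D1:**
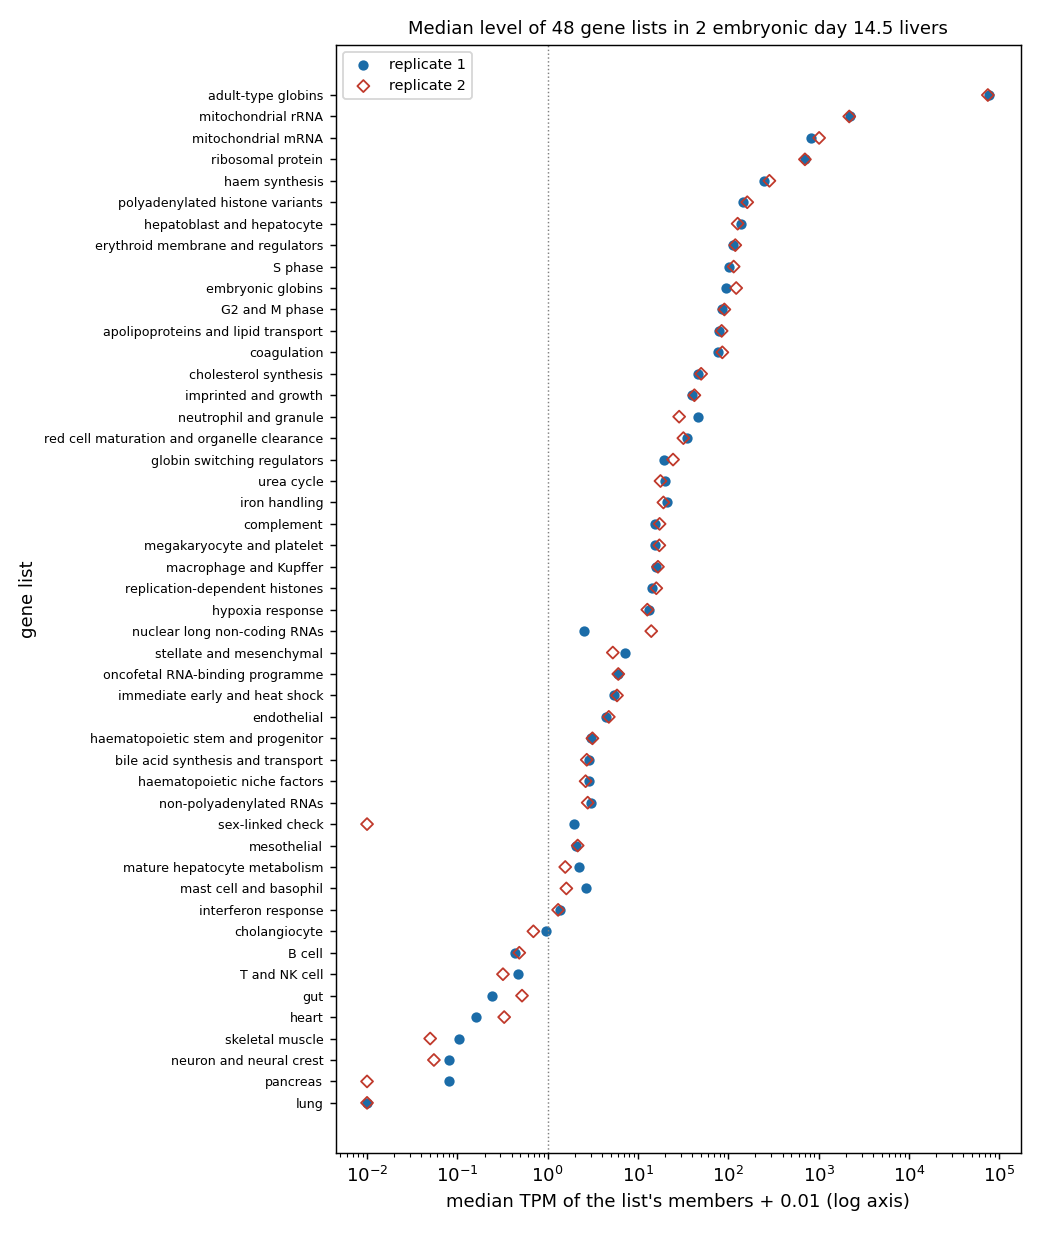
Median TPM of each of the 48 gene lists, with 0.01 added, on a log axis; filled circles are replicate 1, open diamonds replicate 2, and the dotted line marks 1 TPM. Adult-type globins lie at the top near 76338 TPM and lists of neighbouring organs lie below 1 TPM.

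Protein-coding genes held most reads on mouse genes. Their share was 94.7% ± 0.03 (SD, n = 2) of these reads, that of long intergenic RNAs 2.37% ± 0.07 and that of mitochondrial ribosomal RNA 0.653% ± 0.028. Whether RNAs with a poly(A) tail were selected is not given in the sources used here, so these shares need not be those of the total RNA. Mitochondrial mRNAs had a list median of 910 TPM and the 2 mitochondrial rRNAs of 2200 TPM, and ribosomal protein genes had a median of 703 TPM. The list of RNAs without a poly(A) tail had a median of 2.52 TPM, with Rn7sk at 178 ± 6 TPM and no read of Rny3, and replication-dependent histones had a median of 14.9 TPM, against 153 TPM for histone variants with a tail. Not all such RNAs were low: the 7SL members of the fixed list were not matched by symbol, and the 7SL copies Rn7s1 and Rn7s2 were at 5476 ± 242 and 5475 ± 244 TPM, while the histone gene Hist1h2ap, outside the list, was at 5672 ± 46 TPM. The nuclear RNA Malat1 was at 475 ± 12 TPM, and the list of nuclear long RNAs, which holds Xist, had a median of 2.53 TPM in replicate 1 and 14.0 TPM in replicate 2. Spike-ins took 7.35% of reads in replicate 1 and 6.72% in replicate 2. Several rows among the 20 highest, such as Gm28437 and the copies Rn7s1 and Rn7s2, share reads with other loci, with a spread of 31.0%, 39.5% and 39.6% on their estimated counts, and their single values are uncertain.

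By TPM, the share of the most used transcript was close between the livers. Of 22 genes fixed for known promoter or splice choice, 18 had several transcripts and a mean of 5 TPM or more, and by TPM the most used transcript was the same one in both livers in 18 of 18. For Mbnl1 its lead in replicate 2 was small, 25.2% against 24.05%, and by estimated reads another transcript led there, with 37.0% against 35.3%. It held at least 50% in both livers for 13 of them. The leading transcript of Gata1 held 98.7% ± 0.4 (SD, n = 2), that of Slc25a37 94.8% ± 0.7 and Pkm-201 97.1% ± 0.2 of Pkm. Pklr, the liver and red cell pyruvate kinase, was divided between Pklr-201 at 51.8% ± 1.8 and Pklr-202 at 34.7% ± 0.6, and Hnf4a-202 held 94.2% ± 4.4 of Hnf4a. By TPM, the share of the leading transcript differed by a median of 1.97 and at most 8.96 percentage points between the livers. By estimated reads the livers were further apart for Foxp1, where Foxp1-204 led with 38.9% in replicate 1 and 55.3% in replicate 2. Transcript names are from a later annotation release than the one the files used, in which many of these transcripts have another version number, and shares of overlapping transcripts are model estimates.

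The livers were compared gene by gene to describe the spread between replicates. Genes at 1 TPM or more numbered 11613 in replicate 1 and 11763 in replicate 2, with 11323 in both. Across 12053 genes at that level in either library, Pearson's r of log2(TPM + 1) was 0.989 and Spearman's rank correlation 0.987, over genes, which are not independent replicates. Of 5544 genes with a mean of 10 TPM or more, 10 differed at least 2-fold, with 7 lower and 3 higher in replicate 2. Draws with counting noise alone gave a median of 0 such genes and at most 1. Of the 10, only Eif2s3y, Hamp and Kdm6a were protein-coding genes with no reads shared with another locus. The count of 2-fold genes depended on settings: 6 with a pseudocount of 5, 39 from a mean of 1 TPM and 143 with no filter. Hamp, the iron hormone hepcidin (ENSMUSG00000050440.7, chromosome 7, 30942368 to 30944032), was at 25.1 TPM in replicate 1 and 10.1 TPM in replicate 2, from 307 and 86 reads. Hp, the haemoglobin-binding protein haptoglobin, was at 41.0 and 22.9 TPM. Car3 was at 65.5 TPM in replicate 1 and 110.3 TPM in replicate 2. The pseudogenes Gm12191, Rpl30-ps10 and Rpl10-ps1 also lay among the 10, with a spread from shared reads of 46.8%, 43.3% and 93.5% on their counts, and Tceanc2 had 453 and 335 reads, over estimated effective lengths of 553 and 1283 nucleotides.

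White cell granule genes were lower in replicate 2 and platelet genes higher. The neutrophil and granule list had a median log2 ratio of -0.36 (replicate 2 over replicate 1, on TPM + 1), against a central range of 0.00 to 0.15 for random lists matched on mean level, and 16 of 16 members lay below the matched median. S100a8 was at 1292 and 894 TPM, S100a9 at 682 and 479 TPM, and the myeloperoxidase gene Mpo at 302 and 253 TPM. On counts scaled with TMM (trimmed mean of M values) the list median was -0.52. The mast cell and basophil list was lower too, at -0.24, a size that ran from -0.92 with a pseudocount of 0.1 to -0.10 with 5, with the basophil protease gene Mcpt8 at 12.6 and 3.51 TPM. The megakaryocyte and platelet list had a median of 0.34 against a matched range of 0.01 to 0.18, with 16 of 17 members above the matched median, and of 0.22 on TMM-scaled counts. Pf4 was at 338 and 418 TPM, Ppbp at 144 and 180 TPM and Gp9 at 24.1 and 29.7 TPM. The exception, Fli1, named after its values were seen, was at 5.62 and 5.07 TPM. The macrophage and Kupffer list, at 0.04, lay within its matched range.

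Embryonic globins and genes of the red cell membrane and its regulators were slightly higher in replicate 2. The embryonic globins had a median log2 ratio of 0.30 and the erythroid membrane and regulators of 0.15, at the 99.96th and 99.98th percentiles of matched lists. On TMM-scaled counts these medians were 0.18 and 0.04, at the 99.39th and 99.97th percentiles. Haem synthesis had a median of 0.10, at the 98.45th percentile, but of -0.01, at the 84.73th percentile, on TMM-scaled counts. Hbb-y was at 421 and 519 TPM and Hbb-bh1 at 126 and 173 TPM. The adult-type globins, at -0.06, lay at the 4.28th percentile of their comparison lists, and at the 1.94th, outside the central 95%, on TMM-scaled counts. No other gene was as high as these globins, so their comparison lists held lower genes and were not matched on level. S phase genes had a median of 0.13, at the 99.16th percentile, and at the 95.96th on TMM-scaled counts, inside the range. The hypoxia response list had a median of -0.08, at the 0.2th percentile, of -0.17 on TMM-scaled counts and of -0.04 with a pseudocount of 5, with the glycolytic genes Ldha at 900 and 842 TPM and Pgk1 at 113 and 99.8 TPM. The hepatoblast and hepatocyte list, at 0.06, did not stand apart. In all, 10 of 46 lists lay outside the central 95% of matched lists, where 2.3 would be expected by chance for independent lists of independent genes. Matched lists were drawn gene by gene, so a list whose genes vary together lies outside more easily. The matched ranges do not measure the spread between embryos. The other 2 of the 10 are the pancreas list, whose members lay near 0 TPM, and the sex-linked list. The median over compared genes was 0.09 on TPM and -0.02 on TMM-scaled counts, so small list shifts are to be read against their matched lists. The labels give pup number 1 and dam number 2 for both replicates and different collection days. Both livers had the same embryonic age on different days, so they came from different litters. Embryo, litter, collection day and sex-linked reads differ at once and cannot be told apart.

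**Figure D2:**
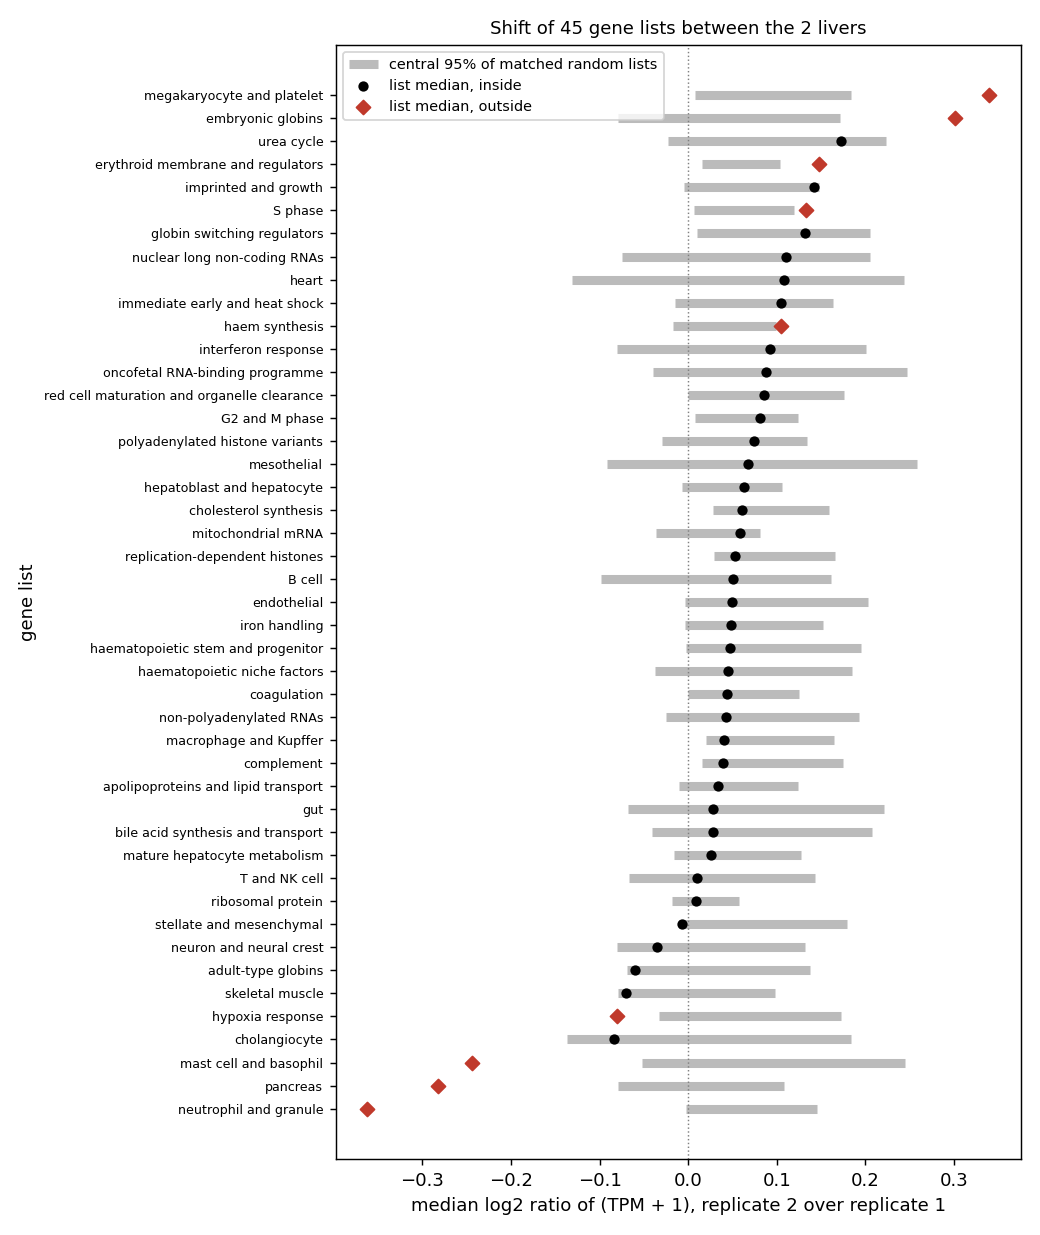
Median log2 ratio of (TPM + 1), replicate 2 over replicate 1, for 45 gene lists, without the sex-linked list. Grey bars are the central 95% of random lists matched on mean level, except that the bar of adult-type globins comes from lower genes. Of these, 9 lists, drawn as diamonds, lie outside their bar, with megakaryocyte and platelet at 0.34 and neutrophil and granule at -0.36.

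**Figure D3:**
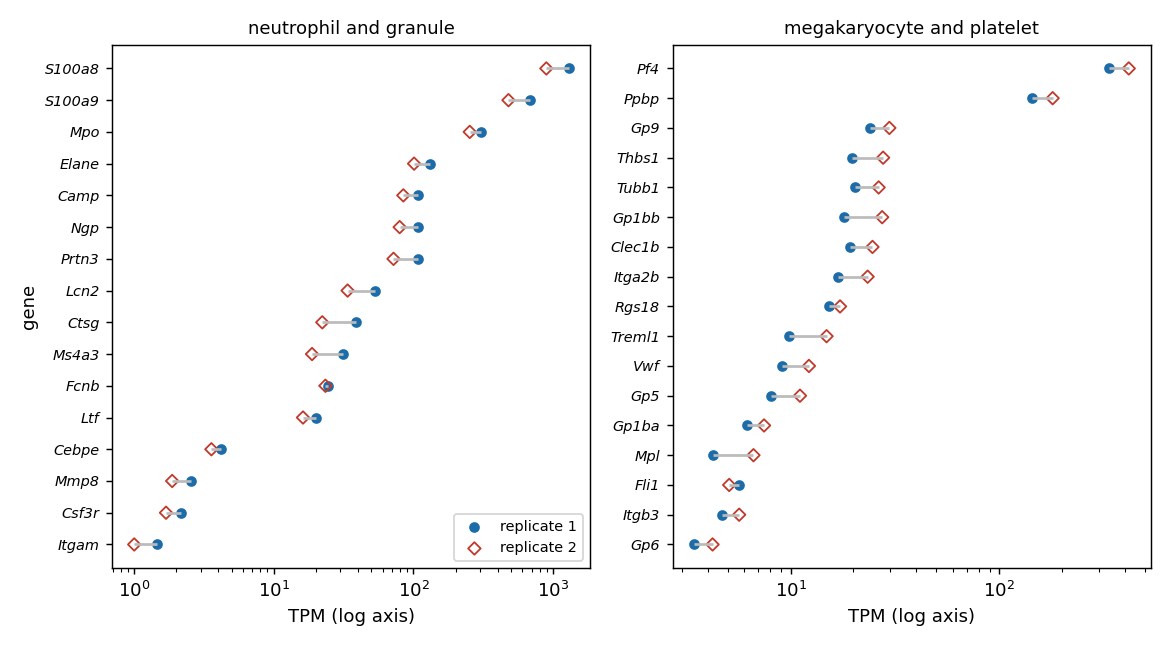
TPM of each member of the neutrophil and granule list (left) and the megakaryocyte and platelet list (right) on log axes; filled circles are replicate 1, open diamonds replicate 2, and lines join the same gene. Neutrophil members were lower in replicate 2 in 16 of 16 genes, and 16 of 17 platelet members were higher.

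Y-linked genes were read in replicate 1 and Xist in replicate 2. Eif2s3y (ENSMUSG00000069049.7, chromosome Y, 1010543 to 1028847) had 1580 reads in replicate 1 and 0 in replicate 2, at least 382-fold lower against a floor of 3 reads per library. Uty had 874 reads and 0, at least 212-fold lower, and Kdm5d 577 reads and 0, at least 140-fold lower. Ddx3y had 1954 reads and 1 read, a ratio of 1419 with an exact 95% interval of 254 to 56068 that covers counting error only. Xist, the RNA that coats the inactive X chromosome (ENSMUSG00000086503.3, chromosome X, 103460366 to 103483254), had 8.90 estimated reads in replicate 1 and 7065 in replicate 2. Kdm6a, the X-linked partner of Uty, was at 8.29 and 18.2 TPM, and Eif2s3x, the X-linked partner of Eif2s3y, at 31.5 and 54.3 TPM.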

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

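No test in this part was chosen after a result was seen. Reads on rows with numeric IDs, which no comparison used, came to 10.09 estimated reads in replicate 1 and 10.0 in replicate 2, above the floor of 3 reads, on 4 and 7 of 26248 such rows. There were no control samples to set them against.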

How the results depend on the processing

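The protein-coding pool, the count of genes with unique reads and the rescaling to mouse genes were added after the data were seen. Over 68 recomputed list shifts of the 10 lists that stood apart, 66 stayed outside the matched range on the same side. Of the 68, 0 crossed to the other side of the median of their matched lists. The haem synthesis median log2 ratio did change sign, from 0.10 to -0.01 with TMM-scaled counts. With TMM-scaled counts, haem synthesis was at the 84.7th and S phase at the 96.0th percentile; the cause was not tested. Globin lists have no value without globin genes, and the pancreas list none at a minimum mean of 1 TPM. Outside the 10 lists, 5 stood apart under some setting, for example ribosomal proteins at the 0.06th percentile with TMM scaling. The imprinted and growth list, inside its range at the 96.36th percentile in the main run, was another. It lay at the 98.71th with a pseudocount of 0.1, the 98.41th with 5 and the 98.2th without globin genes. The count of 2-fold genes was 6 with a pseudocount of 5, 6 with TMM-scaled counts, 39 from a mean of 1 TPM, 143 with no filter and 3 among protein-coding genes with unique reads. The number of detected genes was 7397 at 5 TPM, 15445 at 0.1 TPM and 14188 at 10 or more expected counts. The rank correlation between the livers (Spearman) was 0.994 with TMM-scaled counts and 0.941 with no filter. By expected counts the adult globins took 19.6%, the hepatoblast and hepatocyte list 3.09% and the erythroid membrane list 1.75%, as reads scale with transcript length; without globin genes in the total the last 2 took 2.94% and 1.29%. By expected counts the alpha globin log2 ratio was 11.02. The difference of the erythroid and hepatocyte medians was -0.09 ± 0.19 and was -0.81 over members with a mean of 1 TPM or more, which leaves out low hepatocyte genes. By TPM, spike-ins took 10.0% and protein-coding genes 92.3%. Mean values recomputed from single libraries lay within 1 SD, and with 2 libraries they must; shifts between livers cannot be recomputed without a library.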

Other observations

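The macrophage, Y-linked and escape-gene tests in this part were chosen after their results had been seen; the tests of depth, of gene length and of the acute-phase genes were written before. The 2 smaller sets used below, of escape genes and of acute-phase genes, were added after their members' values had been seen. Genes of pancreas, an organ beside the liver, were seen almost only in replicate 1. Cpa1, a digestive enzyme gene, had 74 reads there and 4 in replicate 2, a ratio of 13.4 per mouse read with an exact 95% interval of 5.03 to 50.6. Cel had 26 reads and 0, at least 6.29-fold lower against 3 reads, and Ins2, an insulin gene, had 10 and 0. The levels were low in both, with Cpa1 at 1.19 and 0.09 TPM. Of the lists of other organs, gut lay at the 41.89th, heart at the 82.3th and neurons and neural crest at the 15.28th percentile of matched lists. The skeletal muscle list, with a median log2 ratio of -0.07, lay inside its range at the 3.9th percentile, but outside it at the 1.69th with a pseudocount of 0.1 and at the 1.59th among lists of protein-coding genes. Only 1 of its 8 members reached 1 TPM in both livers and carries most of the summed level of 20.3 and 22.5 TPM, while the list median was 0.095 and 0.04 TPM, so whether muscle genes were lower in replicate 2 stays open. The cause of the pancreas shift was not tested.

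Neutrophil and granule genes were lower in replicate 2. After replicate 1 was thinned to the depth of replicate 2 the list median was -0.38, still outside its matched range. Thinning keeps the expected TPM, so it covers only the sampling noise of fewer reads and cannot exclude other effects of depth. Among lists matched on level and gene length the lower edge was -0.025, above the observed -0.36, which argues against a length bias. The macrophage list lay at the 7.76th percentile with a median of 0.04, which argues against an equal drop of all white cells, while the mast cell and basophil list fell as well, with a median of -0.24 at the 0.02th percentile, so the drop was not limited to neutrophil genes. A lower share of granulocytes and related cells in that embryo may account for it and stays a hypothesis, since embryo, litter and collection day are confounded.

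Megakaryocyte and platelet genes were higher in replicate 2. Thinning left the list median at 0.32. The upper edge of lists matched on level and length was 0.17, below the observed 0.34. The length match argues against a length bias, while thinning covers only the sampling noise of fewer reads. A larger share of megakaryocytes or platelets may account for it and was not tested. Embryonic globins were higher in replicate 2 as well, at 0.30, while adult-type globins were at -0.06 and neutrophil genes were lower, so whether blood left in the tissue plays a part stays open.

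Y-linked reads in replicate 1 and Xist reads in replicate 2 were set against the label of pooled sexes. The 4 Y-linked genes of replicate 2 summed to 1 read against 4985. The exact upper bound, used in place of the limit for a count of 0, was 0.154% of the level of replicate 1. This is far below the 10% set for tissue of both sexes, a bound fixed after the reads had been seen. Genes known to escape X inactivation had a median log2 ratio of 0.48 at the 100th percentile, and the 4 of 8 whose values had not suggested the list, among them Ddx3x, which had been seen, had 0.28 at the 99.57th, while X-linked genes as a whole were at 0.09 and autosomal genes at 0.10. These values are consistent with a male liver in replicate 1 and a female liver in replicate 2, so sex is a further difference between the replicates. Whether sex bears on the blood cell lists was not tested.

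A weaker acute-phase response in replicate 2 was a hypothesis from the values of Hamp, Hp, Cp and Lcn2. Acute-phase genes not looked at before had a median log2 ratio of -0.057 over 13 measured members, at the 0.8th percentile of matched lists, and of -0.09 over the 8 with a mean of 1 TPM or more, at the 0.19th. The median over the 13 is the value of Orm1, which had 1 read and 0, so it rests on a gene near the floor. Both ranks are on the side the hypothesis predicts, but 5 of the 13 had ratios above 0. These were Lbp at 24.6 and 26.4 TPM, Crp at 31.8 and 32.7 TPM, Saa4, Saa1 and Saa2. Crp (0.04) and Saa4 (0.01) still lay below the median of 0.09 over compared genes. In replicate 2 Saa1 and Saa2 had only 2 and 1 reads, and 0 in replicate 1. The largest falls among the 13 were those of Serpina3n, at 0.73 and 0.16 TPM, Steap4, at 3.67 and 2.40 TPM, and Apcs, at 52.5 and 39.8 TPM. Lcn2, from which the hypothesis came in part, is not among the 13. It also belongs to the neutrophil list, and fewer granulocytes may have lowered it. Whether fewer granulocytes also lowered some of the 13 was not tested.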
